A study of Sus scrofa with 32 samples.

How the data were processed

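RNA sequencing was done on the small intestine of piglets, from a piece taken midway along its length, in 32 libraries of 4 diets that had been fed for 28 days. The diets were milk replacer alone (MR, 7 libraries), milk replacer with liquid feed (MRLF, 8 libraries), liquid feed with benzoic acid (MRLFBA, 8 libraries) and liquid feed with whey (MRLFW, 9 libraries), and the replicate numbers used below are those of the labels. Total RNA was extracted with a Qiagen kit and libraries were prepared by a standard Illumina method, per the labels' protocols. The labels do not say whether each library came from a separate animal, so the p-values below measure the spread between libraries.

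The deposited table holds whole-number read counts per gene symbol for all 32 libraries, not normalized, which the authors made from their reads. The build Sscrofa11.1 and the tool DESeq2 are named without roles, per the submitters' processing notes. The aligner, the counting program, its treatment of strand and of reads that fit several genes, and the annotation are not given in the sources used here. The table had 15648 genes, of which 1 had an empty cell and was not analysed here. Total counts per library ran from 23479893 to 34345096, a 1.46-fold range. Among counts from 1 to 20, 57.8% were even, and 4847 cells of the table held a count of 2 against 1057 that held a count of 1, so the number of molecules behind small counts is uncertain. Gene positions came from a RefSeq gene table of the same build, which listed 14984 of the symbols, and 15517 symbols were in that table or in a table of pig gene names.

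Genes with too few counts were removed with edgeR's filterByExpr by diet (minimum count of 10), which left 13565 genes holding 99.99% of all counts. Libraries were scaled with the trimmed mean of M-values (TMM), and levels are given as CPM, edgeR's counts scaled to a common library size, with the standard deviation (SD). Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, 2-sided, in a fit of all 4 diets that shared a single estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 13565 genes of each comparison and a gene was called at an adjusted p under 0.05. Of the 7 comparisons, 3 were the main ones, in which a single item was added to the diet: liquid feed to milk replacer, benzoic acid to liquid feed, and whey to liquid feed. The other 4 set the mean of the 3 diets with liquid feed against milk replacer and compared the remaining pairs of diets.

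Before the data were examined, 34 gene lists were fixed, covering digestion, metabolism, defence and the cell types of the gut wall. Each list was tested in 4 comparisons with camera of limma 3.58.1 on log2 CPM (prior count of 2), which asks whether the list moved against the other genes, with the correlation between its members estimated from the data. The same test with a preset correlation of 0.01 was an alternative. Counts of members that passed when p-values were adjusted over the list alone are given beside the counts over all genes.

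The genes named in the text followed a rule fixed at the same time. For the main comparisons and the mean of the liquid feed diets, it took up to 12 genes per direction with the largest change among those called with a mean of at least 1 CPM, and up to 2 called members per direction of each list. Where fewer than 10 genes resulted, the genes with the smallest p among those with a mean of at least 1 CPM were added until there were 10, as values that did not pass. Values of 12 genes of digestion, mucus, proliferation, lymphocytes and muscle were to be given in every comparison, of which 10 were tested and the others were not analysed here. Members of lists that are named as examples outside this rule were chosen after their values were seen.

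Alternatives fixed in advance were DESeq2 1.42.0, relative log expression (RLE) factors in edgeR, no filter on low counts, a mean of at least 1 CPM, a fit of the compared diets alone, the replicate number as a block, limma's voom with quality weights, scores of B cell and smooth muscle genes as covariates, and leaving out each library in turn. Chosen after seeing the data were a covariate for a trend with gene span, leaving out 5 libraries rich in B cell genes, and leaving out 135 genes that were near absent in 1 library (at most 3 counts) and abundant in another of the same diet (at least 300 counts). Gene span is the distance from a gene's annotated start to its end. The gene span slope of a library is the slope of each gene's deviation from its mean log2 CPM on its log2 span, over the 13037 tested genes (96.1%) with a known span. The B cell and muscle scores are mean standardized log2 CPM over the members of the lists for those cell types.

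The tests were tested on simulated data drawn from the real means, library sizes and spread (median biological coefficient of variation 32.4%). Among the 13565 genes, 200 single genes were changed, and the members of 5 gene lists were raised 1.5-fold. False calls were counted among the genes left unchanged. Each gene was drawn independently, so trends shared by many genes, such as that with gene span, were absent. The shares and false calls below hold for that setting only. For liquid feed against milk replacer, edgeR recovered 17.9% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 89.4% of those changed 4-fold, with 1 false call. For benzoic acid against liquid feed the shares were 25.4%, 50.7% and 98.5% with 9 false calls, and for whey against liquid feed 22.4%, 71.6% and 93.9% with 8 false calls. For the mean of the liquid feed diets they were 37.3%, 85.1% and 100% with 8 false calls. DESeq2 made 12, 24, 22 and 28 false calls in the same 4 simulations. Figures were drawn with matplotlib 3.10.9.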

Results

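Transcript levels were measured by RNA sequencing in the middle part of the small intestine of piglets after 28 days on 1 of 4 diets. The control diet was milk replacer alone (MR, n = 7 libraries). In the other 3 diets the piglets also had liquid feed, either as such (MRLF, n = 8), with benzoic acid, an acid used as a feed additive (MRLFBA, n = 8), or with whey, the liquid left after milk is curdled (MRLFW, n = 9). Mean total counts per library were 26009800 in MR, 28112100 in MRLF, 29448000 in MRLFBA and 27402700 in MRLFW, and the lowest and highest totals were 23479893 and 34345096. Levels below are CPM after TMM scaling, given with the SD between libraries. Each library was counted as a replicate, and the p-values measure the spread between libraries, since the labels do not state that libraries came from separate animals.

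Libraries of the same diet differed from each other in tissue make-up. The B cell and germinal centre score, a mean over genes such as MS4A1 and CR2, was above 1 in 5 libraries, namely MR 5, MR 6, MRLFBA 5, MRLFW 6 and MRLFW 9, and none of these was an MRLF library. MS4A1, which encodes the B cell surface protein CD20, was between 13.6 and 92.9 CPM in the 5 libraries and at most 1.56 CPM in the other 27. FABP6, an ileal bile acid binding protein, was between 43.6 and 144 CPM in the 5 and at most 23.6 CPM in the others, a level reached in MRLF 1. The first principal component held 31.5% of the variance between libraries and followed the gene span slope, the tendency of genes with a long genomic span to be high in a library. Over the 32 libraries the Pearson correlation of the 2 measures was 0.972 and Spearman's rho was 0.955. Without the 2 libraries farthest from the median slope r was 0.966. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. Both measures come from the same log2 CPM values, so this p cannot show that gene span itself matters. Across genes, the weight in the component had a Spearman correlation of 0.474 with gene span. The mean slope was -0.0467 ± 0.0487 (SD, n = 7) in MR and 0.0414 ± 0.101 (SD, n = 8) in MRLF, a difference with an exact permutation p of 0.0559 and an adjusted p of 0.136 over the 10 tests of 5 library measures. Among the same tests, total counts were lower in MR than in MRLF (exact permutation p = 0.0244, adjusted p = 0.122). They were also lower in MR than in the 3 diets with liquid feed (permutation p = 0.0476, adjusted p = 0.136).

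**Figure D1:**
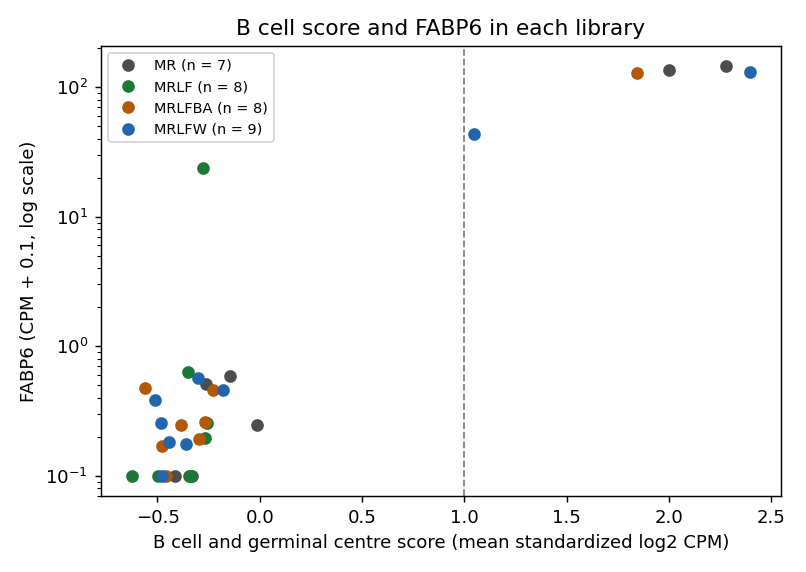
FABP6 in CPM on a log scale (0.1 added) against the B cell and germinal centre score of each of the 32 libraries, coloured by diet, with a dashed line at a score of 1. The 5 libraries to the right of the line had between 43.6 and 144 CPM of FABP6.

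**Figure D2:**
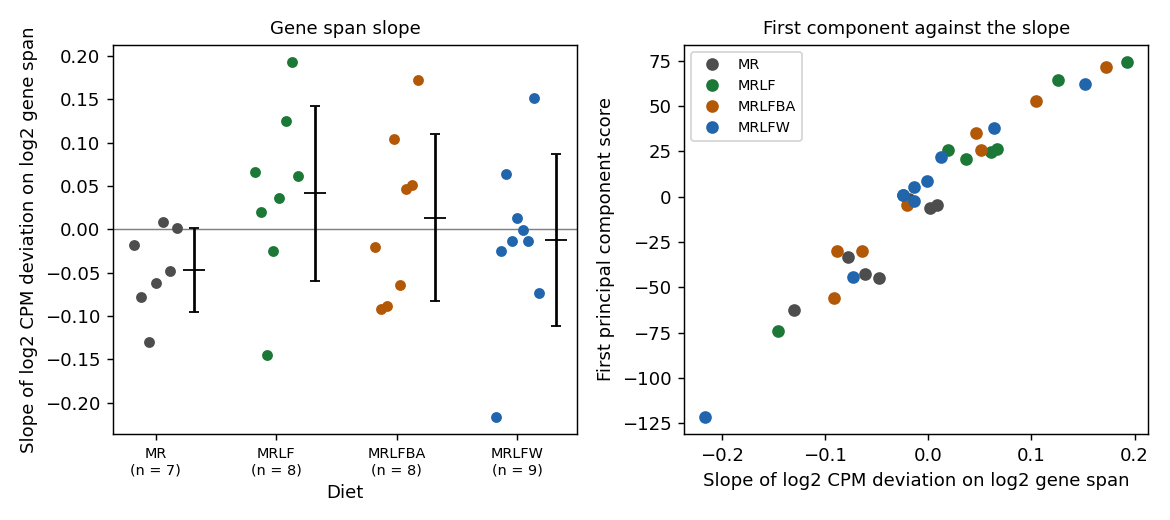
Gene span slope of each library by diet (left; horizontal and vertical bars give the mean and SD) and the first principal component score against that slope (right). Points are libraries, and the component followed the slope with a Pearson correlation of 0.972 over 32 libraries.

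The first comparison asked what liquid feed beside milk replacer did to transcript levels, with 8 MRLF libraries set against 7 MR libraries. PLEKHA6, which encodes a pleckstrin homology domain protein found at cell junctions, rose from 59.9 ± 9.01 CPM (SD, n = 7) to 101 ± 11.8 CPM (SD, n = 8), and all 8 MRLF libraries lay above every MR library. Sucrase-isomaltase (SI) averaged 656 ± 225 CPM in MR and 1310 ± 728 CPM in MRLF, a difference that did not pass and that turned to a log2 fold change of -0.0608 with the gene span slope as a covariate. Most genes of protein digestion and of the interferon response also had higher means in MRLF, without passing the test. B cell genes had lower means in MRLF, where none of the libraries with a high B cell score was found.

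The change in PLEKHA6 was 1.68-fold, a log2 fold change of 0.75 with a standard error of 0.13 and an adjusted p of 0.0414 by edgeR, and it was the 1 gene of 13565 that passed. The gene lies on chromosome 9 from 64876803 to 65027455 in Sscrofa11.1. At an unadjusted p under 0.05 there were 2392 genes, 1434 of them higher and 958 lower in MRLF, where 678 would be expected by chance. A gene span above the median was found in 75.8% of the higher and 28.9% of the lower genes. DESeq2 called 21 genes, 16 higher and 5 lower, and voom with quality weights called 1. PLEKHA6 did not pass with the B cell and muscle scores as covariates (log2 fold change 0.73, standard error 0.14, adjusted p = 0.105), with the gene span slope as a covariate (0.68, standard error 0.13, adjusted p = 0.135), without the 5 libraries rich in B cell genes (0.72, standard error 0.15, adjusted p = 0.278), in a fit of the 2 diets alone (0.77, adjusted p = 0.0591), or in 13 of the 15 fits that left out 1 library. It passed without MRLF 4 (adjusted p = 0.0246) or MRLF 5 (adjusted p = 0.0432). With the replicate number as a block no gene passed.

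**Figure D3:**
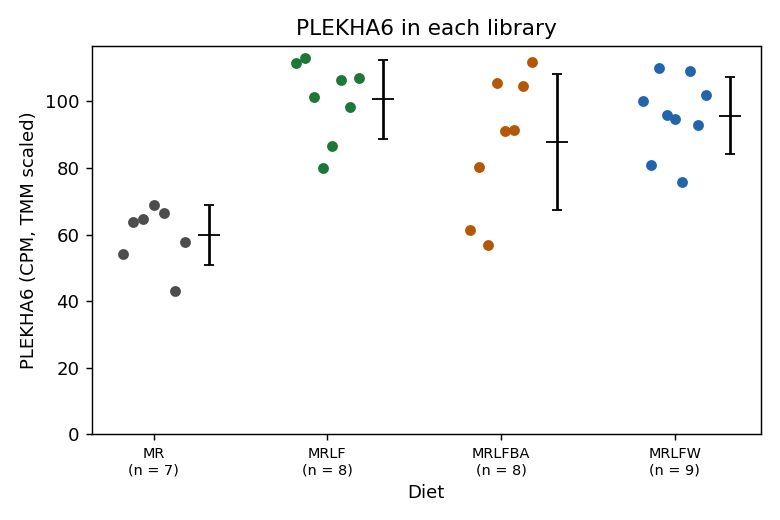
PLEKHA6 in CPM (TMM scaled) in each of the 32 libraries by diet; points are libraries and bars give the mean and SD. All 8 MRLF libraries and 23 of the 25 libraries of the diets with liquid feed lay above every MR library.

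The 9 genes that came next by p shared an adjusted p of 0.244 by edgeR and are given as values. TBC1D8, a gene with a Rab GTPase-activating domain, averaged 79.2 ± 14.4 CPM (SD, n = 7) in MR and 113 ± 9.64 CPM (SD, n = 8) in MRLF, again with all 8 MRLF libraries above every MR library, and its relative TBC1D8B averaged 12.5 and 23.3 CPM. PLB1, a phospholipase of the brush border, averaged 6.74 ± 2.52 CPM in MR and 17.5 ± 8.94 CPM in MRLF, a log2 fold change of 1.38. CDCP1 and HMBOX1 had log2 fold changes of 1.03 and 0.72. Lower means in MRLF were found for PON1, a paraoxonase (log2 fold change -1.12), for B3GAT2, a glucuronyltransferase (-0.73), and for the homeobox gene HOXB7 (-0.84). EFCAB7, an EF-hand gene, had a log2 fold change of 4.30 (standard error 1.11) and fell into separate classes of libraries. It was between 1484 and 6403 counts in 12 libraries, of which 7 were MRLF, 1 was MRLFBA and 4 were MRLFW, and between 20 and 255 counts in the other 20, which included all 7 MR libraries.

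Most genes of protein and sugar digestion had higher means in MRLF, without either list passing. Of 24 genes of protein digestion and amino acid uptake, 19 had a positive log2 fold change (median 0.45), with 8 higher and 0 lower at an unadjusted p under 0.05, and 1 member, TMPRSS15, passed when adjusted over the list alone. TMPRSS15, the enteropeptidase that activates trypsin, averaged 13.0 ± 8.62 CPM in MR and 36.7 ± 12.9 CPM in MRLF. Of 11 genes of sugar digestion and uptake, 9 were positive (median 0.46), and MGAM2, a maltase-glucoamylase gene, and SLC2A2, the basolateral glucose transporter, were 2 members that passed when adjusted over the list alone. SLC2A2 averaged 78.4 ± 41.3 CPM in MR and 171 ± 70.6 CPM in MRLF. The lactase gene LCT averaged 2185 ± 864 and 2957 ± 943 CPM, the glucose transporter gene SLC5A1 770 ± 407 and 1031 ± 435 CPM, and SI had a log2 fold change of 1.00 with an adjusted p of 0.270 (-0.0608 with the gene span slope as a covariate). Among 12 genes of fructose metabolism and gluconeogenesis, TXNIP and ARRDC4, both of which respond to glucose in cells, passed when adjusted over the list alone, with log2 fold changes of 1.40 and 0.51. Of 23 genes of lipid uptake and chylomicron assembly 15 were positive, among them APOB (0.99) and MTTP (0.88), while APOA4 was at 11575 ± 10266 and 10430 ± 4129 CPM, with 8136 CPM in MR when MR 3 was left out. The preset correlation called the protein (adjusted p = 0.00023), sugar (0.0283) and lipid (0.0213) lists, but each had an adjusted p = 0.802 with an estimated correlation.

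**Figure D4:**
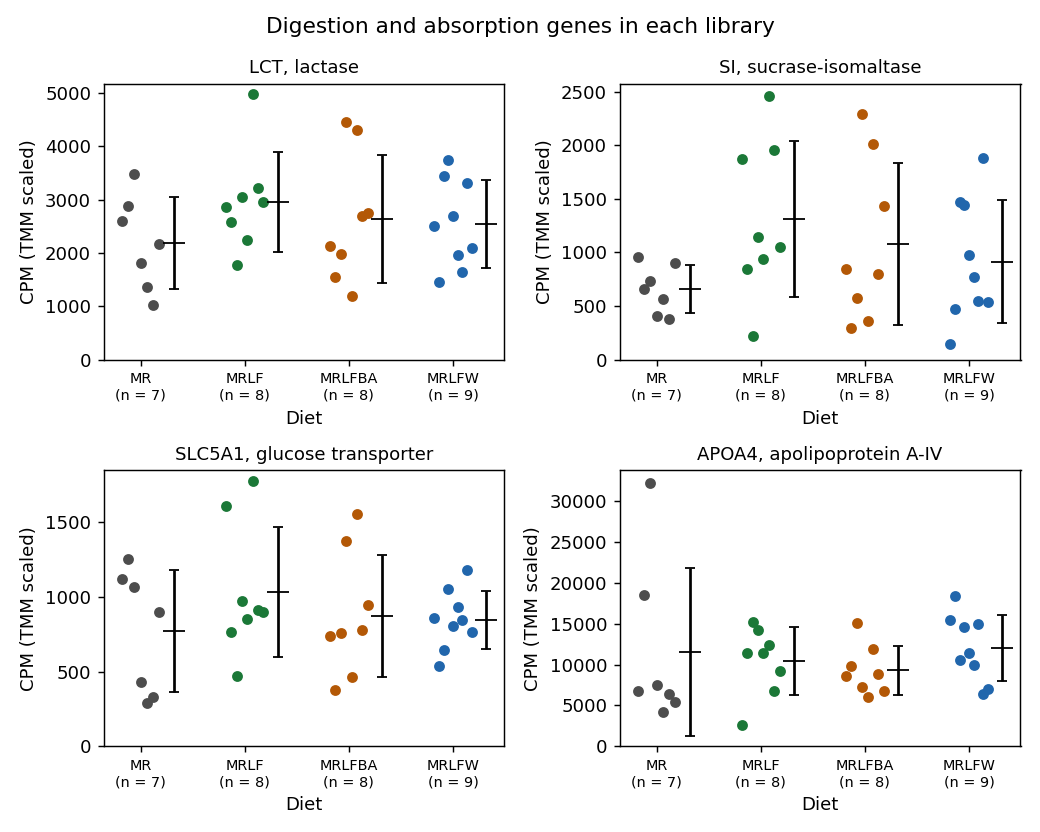
LCT, SI, SLC5A1 and APOA4 in CPM (TMM scaled) in each of the 32 libraries by diet, with bars for the mean and SD. SI averaged 656 CPM in MR and 1310 CPM in MRLF (log2 fold change -0.0608 with the gene span slope as a covariate), and the ranges of the diets overlapped for all 4 genes.

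Immune genes had higher means in some lists and lower means in others, without any list passing. Of 32 interferon response genes 31 had a positive log2 fold change (median 0.81) and 8 were higher at an unadjusted p under 0.05, among them RSAD2, which averaged 42.0 ± 54.2 CPM in MR and 139 ± 104 CPM in MRLF. All 18 B cell and germinal centre genes had a negative log2 fold change (median -3.18) and 15 of them passed when adjusted over the list alone, MS4A1 averaging 22.7 ± 37.6 CPM in MR and 0.978 ± 0.296 CPM in MRLF, with 2 of the 7 MR libraries carrying the high values and a log2 fold change of 0.35 without the 5 libraries rich in B cell genes. All 10 genes of MHC class II (median -0.50) and all 7 of plasma cells (median -0.29) were negative, and the plasma cell genes DERL3 and POU2AF1 were 2 that passed when adjusted over the list alone. The T cell gene CD3E was at 86.2 ± 38.3 and 70.3 ± 24.8 CPM. The interferon, B cell, MHC class II, plasma cell and antimicrobial lists were called with the preset correlation but had an adjusted p = 0.802 with an estimated correlation.

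The remaining lists gave no call in either form apart from mature enterocyte genes, of which 11 of 15 were positive (preset adjusted p = 0.039, adjusted p = 0.802 with an estimated correlation), so that 9 of 34 lists were called with the preset correlation and 0 with the estimated one. Single members passed when adjusted over the list alone in 3 further lists. In the list for goblet cells it was CLCA4 (1506 ± 513 CPM in MR, 3878 ± 1591 CPM in MRLF). Whether goblet cells carried the higher mean of CLCA4 was not tested. The others were the crypt genes RNF43 (log2 fold change 1.20) and EPHB3 (-0.56), and the xenobiotic enzyme gene CYP1A2 (-2.44, at 1.78 and 0.325 CPM). Mucin 2 (MUC2, log2 fold change -0.27), the immunoglobulin receptor PIGR (0.27), the proliferation gene MKI67 (-0.14) and the smooth muscle gene MYH11 (-0.13) differed by less than their standard errors. With the gene span slope as a covariate MUC2 turned to 0.28, MKI67 to 0.11 and APOA4 to 0.30. MYH11 turned to 0.14 with the B cell and muscle scores as covariates and to 0.34 without the 5 libraries rich in B cell genes.

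The second comparison asked what benzoic acid added to the liquid feed, with 8 MRLFBA and 8 MRLF libraries. No gene passed in edgeR, and the largest shift by p was in SLC1A1, the glutamate and aspartate transporter of the brush border, which averaged 87.8 ± 43.7 CPM (SD, n = 8) in MRLF and 29.9 ± 21.3 CPM (SD, n = 8) in MRLFBA. Protein digestion genes had lower means with benzoic acid in 23 of 24 cases. Genes of the list for benzoate activation and glycine conjugation, which also holds other genes such as acid carriers, had slightly higher means in 7 of 8 cases. Neither list passed with an estimated correlation. The mean log2 CPM of the protein digestion list was 6.45 in MR, 6.88 in MRLF and 6.33 in MRLFBA, so MRLF was the highest of these diets. The mature enterocyte list was at 8.61 in MRLF and 8.43 in MRLFBA, and the crypt and stem cell list at 4.42 and 4.63.

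SLC1A1 had a log2 fold change of -1.55 (standard error 0.40), with 6 of the 8 MRLFBA libraries below every MRLF library, and an adjusted p of 1.00 by edgeR over all genes. It was the 1 member of its list that passed when adjusted over the list alone. Of 15 antimicrobial defence genes 12 were positive, 2 of them at an unadjusted p under 0.05 (adjusted p = 0.528 with an estimated correlation). Among the single genes next by p with a mean of at least 1 CPM, BPI, a bactericidal protein, averaged 203 ± 93.5 CPM in MRLF and 391 ± 143 CPM in MRLFBA, and FCN1, a lectin of the complement system, averaged 4.07 ± 2.97 and 10.6 ± 7.37 CPM. REG3G, an antimicrobial lectin, averaged 15.7 ± 18.8 and 137 ± 283 CPM, and its higher mean rested on 2 of the 8 MRLFBA libraries. TBXAS1, the thromboxane synthase gene (log2 fold change 0.51), and ARPIN (0.44) also had higher means. Lower means were found for the anion exchanger gene SLC26A6 (-0.75), FAM151A (-2.83), which averaged 5.97 CPM in MRLF and 3.37 CPM there without MRLF 1, and for LUZP2 (-1.11) and PLPPR5 (2.08 ± 0.803 and 1.04 ± 0.476 CPM in MRLF and MRLFBA). The median log2 fold change of the 24 protein digestion genes was -0.36 and that of the 8 benzoate genes 0.21, each with an adjusted p = 0.112 with an estimated correlation. Among the benzoate genes, SLC5A8 and SLC16A1, carriers of short-chain acids, had log2 fold changes of 0.21 and 0.22. All 11 sugar genes (median -0.24) were negative and all 7 plasma cell genes (median 0.53) were positive, with an adjusted p = 0.401 and 0.176 with an estimated correlation. The immunoglobulin joining chain gene JCHAIN averaged 311 ± 205 CPM in MRLF and 514 ± 112 CPM in MRLFBA. Genes of the enteric nervous system were negative in 12 of 12 cases (median -0.46, adjusted p = 0.272 with an estimated correlation), as were 12 of 14 smooth muscle genes (median -0.31, adjusted p = 0.401 with an estimated correlation). Of the cell cycle genes 26 of 27 were positive by small amounts (median 0.11, adjusted p = 0.585 with an estimated correlation). LCT (log2 fold change -0.17), SI (-0.28), SLC5A1 (-0.24), APOA4 (-0.17), PIGR (0.21), MKI67 (0.07), CD3E (-0.10) and MYH11 (-0.44) differed by less than their standard errors, and MUC2 averaged 250 ± 94.3 and 327 ± 144 CPM. MS4A1 averaged 7.18 ± 18.4 CPM in MRLFBA, with 52.6 CPM in MRLFBA 5 alone.

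With edgeR 0 genes were called and 148 had an unadjusted p under 0.05, fewer than the 678 expected by chance, while voom with quality weights called 0 and DESeq2 called 4. These were PLA2G2A (833 to 2677 counts in 4 libraries, 0 in 28), PAEP and CBD139, which had counts only in the 5 libraries rich in B cell genes, and CCDC81 (983 to 1668 counts in 4 libraries, 18 to 125 in 28), genes chosen after their values were seen. Among the 148 genes, 32.4% of those higher and 70.6% of those lower with benzoic acid had a gene span above the median. The preset correlation called 19 of 34 lists and the estimated one 0. With the B cell and muscle scores as covariates the protein digestion list passed, with an adjusted p = 0.0409 with an estimated correlation.

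The third comparison asked what whey added to the liquid feed, with 9 MRLFW and 8 MRLF libraries. No gene passed in edgeR. SLC1A1 again had a lower mean, 37.9 ± 19.8 CPM (SD, n = 9) against 87.8 ± 43.7 CPM (SD, n = 8) in MRLF, with 5 of 9 MRLFW libraries below every MRLF library. Cholesterol biosynthesis genes had higher means with whey in 22 of 24 cases, and genes of B cells and of inflammatory cytokines had higher means in 18 of 18 and 20 of 21 cases, without passing as lists.

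Among the genes first by p with a mean of at least 1 CPM, PLPPR5 (log2 fold change -1.40, 2.08 CPM in MRLF and 0.782 CPM in MRLFW) and SOGA3 (-1.13) had lower means, and SLC1A1 had a log2 fold change of -1.21, all with an adjusted p of 0.887 by edgeR. COL18A1, which encodes a basement membrane collagen, averaged 2348 ± 1055 CPM in MRLF and 7180 ± 7131 CPM in MRLFW. The potassium channel gene KCNK6 (log2 fold change 0.72) and the receptor gene RELT (1.18) also had higher means. COL18A1 was highest in MRLFW 9, and KCNK6 and RELT in MRLFW 6, libraries rich in B cell genes. Without the highest library COL18A1, KCNK6 and RELT averaged 5613, 17.4 and 6.75 CPM in MRLFW. Their means over all MRLF libraries were 2348, 12.2 and 3.48 CPM. The B cell receptor genes CXCR5 and TNFRSF13C and the IgE receptor gene FCER2 averaged 3.36, 8.86 and 4.31 CPM in MRLFW, and without MRLFW 6 they averaged 0.698, 3.34 and 0.534 CPM. TAF2 averaged 0.225 CPM in MRLF and 5.50 CPM in MRLFW, where 3 libraries carried it. The cholesterol list had a median log2 fold change of 0.32 and an adjusted p = 0.633 with an estimated correlation, and its members HMGCS1 and SQLE, enzymes of cholesterol synthesis, had values of 0.38 and 0.33. The B cell list had a median of 2.49 (adjusted p = 0.749 with an estimated correlation), and 12 of its 18 members passed when adjusted over the list alone. The high values came from MRLFW 6 and MRLFW 9. All 7 plasma cell genes (median 0.64) and all 10 genes of MHC class II (median 0.39) were positive, each list with an adjusted p = 0.633 with an estimated correlation. The plasma cell list was the 1 list with an unadjusted p under 0.05 (0.0248). Of 22 T and NK cell genes 19 were positive (median 0.45, adjusted p = 0.633 with an estimated correlation), and CD3E averaged 70.3 ± 24.8 and 88.9 ± 42.7 CPM. The chemokine gene CCL20 averaged 32.3 ± 15.5 CPM in MRLF and 79.6 ± 61.3 CPM in MRLFW, and the cytokine list had a median of 0.54 (adjusted p = 0.749 with an estimated correlation). Protein digestion genes were negative in 21 of 24 cases (median -0.28, adjusted p = 0.633 with an estimated correlation). LCT (log2 fold change -0.22), SLC5A1 (-0.29), APOA4 (0.21) and PIGR (-0.31) differed by less than their standard errors, and SI (-0.52), MUC2 (0.63), MKI67 (0.43), MS4A1 (3.66) and MYH11 (-0.54) did not pass. Without MRLFW 1 the MRLFW means of MUC2 and MKI67 were 285 and 128 CPM instead of 386 and 161 CPM, beside 250 and 119 CPM in MRLF.

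For whey, edgeR called 0 genes and 373 had an unadjusted p under 0.05, voom with quality weights called 0, and DESeq2 called 5, which were the 4 that it called for benzoic acid and GREB1L. This gene was first by p in edgeR too (adjusted p = 0.645) but had a low mean, 1.15 ± 0.482 CPM in MRLF and 0.407 ± 0.0700 CPM in MRLFW, and was named after its values were seen. Among the 373 genes, 33.0% of those higher and 69.2% of those lower with whey had a gene span above the median. The preset correlation called 13 of 34 lists and the estimated one 0.

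The effects of benzoic acid and of whey were also set beside each other, because both were measured against the same 8 MRLF libraries. Across the 13565 genes, which are not independent replicates, their log2 fold changes had a Pearson correlation of 0.641 and a covariance of 0.0609. Unchanged groups were simulated by shuffling the libraries of MRLF, MRLFBA and MRLFW after the mean of each diet was removed. Set against a shared group of shuffled libraries, they gave a mean correlation of 0.508 and a mean covariance of 0.0629. In 42 of 100 simulations the covariance was at least as large as that observed. With the MRLF libraries split into 4 and 4, so that the comparisons shared none, the mean correlation over 70 splits was 0.0694, between -0.294 and 0.275. The lower means of SLC1A1 with both additions rested on the same MRLF libraries, and SLC1A1 averaged 45.7 ± 17.3 CPM (SD, n = 7) in MR, nearer to those 2 diets than to MRLF. The same MRLF libraries gave the highest protein digestion level and the lowest plasma cell level of the diets. Mean log2 CPM in MR, MRLF, MRLFBA and MRLFW was 6.45, 6.88, 6.33 and 6.54 for protein digestion. For plasma cells it was 5.34, 4.51, 5.17 and 5.25. COL18A1, KCNK6 and RELT averaged 7163, 18.9 and 8.32 CPM in MR, near their MRLFW means of 7180, 20.1 and 7.90 CPM. In both diets the highest library for each gene was rich in B cell genes, and MRLF had no such library. The highest were MR 6 and MRLFW 9 for COL18A1, MR 5 and MRLFW 6 for KCNK6, and MR 6 and MRLFW 6 for RELT.

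The mean of the 3 diets with liquid feed was then compared with milk replacer, 25 libraries against 7. PLEKHA6 rose from 59.9 ± 9.01 CPM (SD, n = 7) to 94.7 ± 15.3 CPM (SD, n = 25), and 23 of the 25 libraries lay above every MR library. Lower means were found for FKBP1B, a binding partner of calcium release channels, and for the neuronal gene GAP43, and genes of enteric neurons and glia were negative in 11 of 12 cases. Interferon response genes were positive in 31 of 32 cases.

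PLEKHA6 was 1.58-fold higher (log2 fold change 0.66, standard error 0.11, adjusted p = 0.0252 by edgeR) and was the 1 gene that passed. FKBP1B averaged 8.05 ± 2.68 CPM in MR and 4.58 ± 1.11 CPM in the diets with liquid feed (adjusted p = 0.0692). PON1 averaged 6.00 ± 2.36 and 2.95 ± 1.09 CPM, and GAP43 11.4 ± 5.73 and 5.74 ± 2.07 CPM. PTX3, a pentraxin of innate defence, had a log2 fold change of -1.69, which rested on 83.9 CPM in MR 2. Without that library it averaged 5.40 CPM in MR, against 5.13 CPM in the diets with liquid feed. PLB1 (log2 fold change 1.34), CDCP1 (0.96), SHROOM3 (0.64), HMBOX1 (0.63) and TBC1D8 (0.42) had higher means without passing. In the list of enteric neurons and glia, 5 of 12 members, UCHL1, SNAP25, VIP, GFAP and PRPH, had lower values that passed when adjusted over the list alone, with a list median of -0.69. Smooth muscle genes were negative in 10 of 14 cases (median -0.31), MYH11 averaging 1835 ± 964 and 1346 ± 816 CPM. In the unfolded protein response list, DNAJB9, DNAJC3 and HYOU1, which encode chaperones of the endoplasmic reticulum, were 3 of 17 members that passed when adjusted over the list alone (log2 fold changes 0.97, 0.34 and 0.56). RNF43 and TMPRSS15 passed in their lists again, as did CLCA4 and ATOH1, the transcription factor of secretory cells, in the goblet cell list. The interferon list (median 0.64), the B cell list (median -1.72, 17 of 18 negative, 13 members passing when adjusted over the list alone, with MS4A1 at 81.1 CPM in MR 5, 74.2 CPM in MR 6 and at most 1.21 CPM in the other 5 MR libraries) and the neuron, muscle and unfolded protein lists were called with the preset correlation, and each had an adjusted p = 0.718 with an estimated correlation. LCT (log2 fold change 0.31), SI (0.73), SLC5A1 (0.25), APOA4 (-0.14), MUC2 (0.07), PIGR (0.24), MKI67 (0.03), MS4A1 (-2.36) and CD3E (-0.21) did not pass.

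In this comparison 2333 genes had an unadjusted p under 0.05, DESeq2 called 47 genes (42 higher, 5 lower) and voom with quality weights called 1909 (968 higher, 941 lower), while 13 of 34 lists were called with the preset correlation and 0 with the estimated one. PLEKHA6 did not pass with the gene span slope as a covariate (log2 fold change 0.61, adjusted p = 0.05001), without the 5 libraries rich in B cell genes (0.64, adjusted p = 0.135), or when MR 1, MR 2, MR 3, MR 6, MR 7 or MRLF 1 was left out (adjusted p up to 0.0954). With the replicate number as a block no gene passed here either.

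In the remaining pairs of diets no gene passed in edgeR. The benzoic acid diet against milk replacer had 1279 genes at an unadjusted p under 0.05, with 4 genes called by DESeq2, namely FKBP1B, NCCRP1, KIRREL3 and HSP70, and 2 called by voom with quality weights, CHRM4 and FKBP1B. NCCRP1 averaged 4.09 ± 1.59 CPM in MR and 1.38 ± 0.465 CPM in MRLFBA (log2 fold change -1.57, adjusted p = 0.342 by edgeR) and was called in edgeR with the B cell and muscle scores as covariates (adjusted p = 0.0139). The whey diet against milk replacer had 1025 such genes, with 2 called by DESeq2, PLEKHA6 and PLB1, and 3 called by voom, CHRM4, PLEKHA6 and SERPINF1. The whey diet against the benzoic acid diet had 154 such genes and 0 were called by DESeq2 or by voom. These genes were chosen after their values were seen. LCT averaged 2631 ± 1199 CPM (SD, n = 8) in MRLFBA and 2538 ± 824 CPM (SD, n = 9) in MRLFW, and SI 1077 ± 754 and 915 ± 570 CPM, values that lay within 1 standard deviation of each other. SLC5A1 averaged 872 and 844 CPM, APOA4 9280 and 12063 CPM, MUC2 327 and 386 CPM, PIGR 350 and 244 CPM, MKI67 125 and 161 CPM, MS4A1 7.18 and 12.4 CPM, CD3E 65.6 and 88.9 CPM and MYH11 1237 and 1154 CPM in the same order.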

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

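All tests of explanations in this part were chosen after the result was seen. A library was singled out where its gap to the nearest other library of its diet was a large share of the diet's whole range, above Dixon's 95% critical value. This was so for 17 of 146 values, where 7.3 would be expected because chance alone singles out about 1 in 20 groups. The share is given in brackets after each library.

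Among the lymphocyte genes, MRLFBA 5 lay far above the other MRLFBA libraries in its B cell score (0.863) and in MS4A1 (0.721), MRLFW 6 was high in TNFRSF13C (0.522), and MR 1 was high in CD3E (0.62). Among the genes of digestion and mucosal defence, MRLF 3 was low in SI (0.559), MRLF 1 was low in APOA4 (0.53), MRLFW 1 was high in PIGR (0.53) and MRLF 5 was low in BPI (0.551). MR 2 was high in PTX3 (0.764), MR 6 was high in FKBP1B (0.654), MR 1 was low in HOXB7 (0.788), MRLF 4 was low in EFCAB7 (0.607), MRLF 2 was low in MYH11 (0.545) and MRLFW 8 was low in RELT (0.52). MRLFW 1 also had the lowest TMM factor of its diet (0.606), a high MKI67 (0.499) and a low SOGA3 (0.51), so that 4 of the 17 values were from this library, whose TMM factor was 0.774.

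The 5 libraries with a B cell score above 1 were weighed further. GP2, a gene of the M cells that cover lymphoid follicles, was above all other libraries in 4 of the 5, which is consistent with a lymphoid follicle in the piece of gut that was taken. A position nearer the ileum was left open, since FABP6 was high in all 5 but only 1 of 3 other ileal genes, FGF19, had a higher median in them, at 0.152 against 0.0841 CPM. MRLF 1 had 23.6 CPM of FABP6 and 17.6 CPM of GP2 with a low B cell score of -0.276, so these markers were also seen apart from B cell genes. Diet was left open as well, since 5 libraries are too few to decide. The largest share of such libraries in a diet was 28.6%, in MR, against 0 of 8 in MRLF (Fisher's exact p = 0.534 over the 4 diets), and the B cell score was lower in MRLF than in MR with an exact permutation p of 0.0118 (adjusted p = 0.118 over 10 tests).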

How the results depend on the processing

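The gene span covariate, the fits without 5 libraries rich in B cell genes and those without 135 on/off genes were chosen after seeing the data. PLEKHA6 had a higher level with liquid feed in every fit. For liquid feed against milk replacer, the count of genes called was 0 with the replicate block, the composition covariates or the gene span covariate, 21 with DESeq2, and 0 to 1 when 1 library was left out. The same count for the mean of the liquid feed diets was 0 with the block or the gene span covariate, 2 without the 5 libraries (RABGAP1 and PTX3), 47 with DESeq2, 1909 with voom, and 0 to 2 when 1 library was left out. Without the 5 libraries RABGAP1 was the 1 gene called for liquid feed against milk replacer, and EFCAB7 was the 1 gene called in a fit of those diets alone. DESeq2 called 4 genes for benzoic acid and 5 for whey against liquid feed. Against milk replacer the benzoic acid diet had 1 with the composition covariates, 4 with DESeq2 and 2 with voom, and the whey diet had 2 and 3 with the latter tools. Lists called with the preset correlation were 9, 19, 13 and 13. With the estimated correlation, 1 list was called for benzoic acid when the composition covariates were used. The correlation of the benzoic acid and whey effects was 0.0694 with the MRLF libraries split, which removes the shared libraries.

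Of 533 values of 50 named genes and comparisons, 523 kept their direction, 8 were no longer past the threshold and 24 became so. Reversed were, for liquid feed against milk replacer, SI (-0.0608), APOA4 (0.30), MUC2 (0.28) and MKI67 (0.11) with the gene span covariate, APOA4 with the block (0.15) and with voom (0.0940), and MS4A1 and MYH11 with the composition covariates (0.48 and 0.14) and without the 5 libraries (0.35 and 0.34). The 5 libraries and the composition scores carry the B cell genes themselves; for the other values the cause was not tested. Replicate numbers showed no clear pairing of libraries. Over 44 pairs with the same number the mean correlation was 0.0112, against 0.00152 for pairs with other numbers, and 6 libraries correlated best with their own number. The same-number correlations ran from -0.526 to 0.528, so an effect shared by libraries of the same number was not excluded.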

Other observations

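All tests of explanations in this part were chosen after the result was seen, and so were the genes named here. Fat tissue genes stood out in single libraries of several diets. ADIPOQ, which encodes the adipocyte hormone adiponectin, had 5218 counts in MRLFBA 1, 863 in MRLF 1, 861 in MRLFBA 4, 776 in MRLF 4 and 514 in MR 2. A score of 7 adipocyte genes was 1.69, -0.0314, 0.721, 1.04 and 0.803 in these libraries, so MRLF 1 was not high in the score. The fat cell genes PLIN1 and FABP4 were high there, however, with 192 and 821 counts in MRLF 1 beside 198 and 854 in MR 2.

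Some genes fell into high and low classes of libraries. EFCAB7, with 20 to 255 counts in its low class, was high in 0 of 7 MR, 7 of 8 MRLF, 1 of 8 MRLFBA and 4 of 9 MRLFW libraries, a spread for which it was picked out of all genes. Others were abundant or near absent. EIF1AX, a translation initiation factor gene, had 2222 to 3951 counts in 11 libraries and 0 to 13 in the other 21. The prion protein gene PRNP had 1052 to 2532 counts in 24 libraries and 0 to 4 in 8. CMTR2, an mRNA cap methyltransferase gene, had 224 to 1250 counts in 18 libraries, among them all 7 of MR, and 0 in 14. In 16 libraries TTC19 had 387 to 813 counts and ADORA2B, 13013 bp away on chromosome 12, had 10 to 217, while in the other 16 TTC19 had 0 to 46 and ADORA2B 622 to 1131. CCDC81, low but not absent in most libraries, had 983 to 1668 counts in 4 libraries in which HIKESHI, 518 bp away on chromosome 9, had 70 to 339, while in the other 28 CCDC81 had 18 to 125 and HIKESHI 1028 to 2085.

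For the 128 tested genes with at most 3 counts in 1 library and at least 300 in another of the same diet, among which EFCAB7 and CCDC81 are not, 3 explanations were weighed. Reads booked under a flanking gene were looked for among the nearest tested genes with a known position on each side. Of 124 genes with a known position, 18 had such a neighbour with a correlation under -0.5, against 5 with random genes. For most no such neighbour was found. Genes not listed or removed by the filter could not be seen, and an abundant neighbour would change little. This explanation was therefore left open. Lymphoid tissue was argued against as the cause for most, since 20 of 128 correlated above 0.5 with the B cell score, although this was a larger share than the 6.199% of other genes. Ileal tissue apart from B cell genes was not tested, since the score holds no ileal gene. Diet was left open: 7 of 128 were spread unevenly over the diets at an exact p under 0.05 where 6.4 would be expected, but the genes had been chosen for varying within a diet. Inherited differences between piglets were not tested.

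More genes than expected had a small p-value in the comparisons with milk replacer. For the benzoic acid and whey diets the counts, 1279 and 1025, were reached in 13 and 23 of 100 splits (highest others 3394 and 4535), so chance was not excluded. For liquid feed against milk replacer 2392 genes had an unadjusted p under 0.05, and 4 of 100 splits of the libraries had as many (highest other 4026). This is under the limit of 5 of 100 for this count alone, with no allowance for the other counts tested. The splits were drawn at random and 4 lies near the limit, so chance was not firmly excluded. In the fit with the gene span slope as a covariate 811 genes had such a p, a count that 32 of 100 splits reach. The gene span trend was thus left open as a cause. In the fit with the composition scores 1779 had, which 8 of 100 reach. Most of the count of 2392 remained there, and 4 and 8 of 100 both lie near the limit, so that fit does not decide on composition. For the mean of the liquid feed diets 2333 genes had such a p and 2 of 100 splits had as many (highest other 2867), which is under the limit in the same sense. There the count was 1478 in the fit with the gene span slope (8 of 100 splits), which leaves that trend open. It was 2013 in the fit with the composition scores (4 of 100), close to the limit of 5. These scores hold only B cell and smooth muscle genes, so the fit cannot decide on composition as a whole. RNA quality and library preparation were not tested, since no measure of them is given in the sources used here.

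The libraries were also split in other ways to see how often a count of calls arose. For liquid feed against milk replacer 3 of 100 splits had at least the 1 gene called (highest other 2). This is under the limit of 5 of 100 for this comparison alone, with no allowance for the 7 comparisons. It lies near the limit, so chance was not firmly excluded. For the mean of the liquid feed diets 10 of 100 had at least 1 gene (highest other 1), so chance was not excluded. In the other 5 comparisons the real count was 0, which 100 of 100 splits reach, and the highest other counts were 0 for benzoic acid and 1767 for whey against liquid feed, 2 and 66 for these diets against milk replacer, and 17 for whey against benzoic acid. A split with 1767 genes points to a structure of the libraries other than diet. Its difference in gene span slope, 0.125, ranked 2 of 100, but the splits with 66 and 17 genes ranked 85 and 51, so the slope does not account for those. For lists the real count was 0 in all 4 comparisons, which 100 of 100 splits reach, and the highest other count was 1. The 1909 genes called by voom for the mean of the liquid feed diets were reached in 6 of 100 splits (highest other 4572), so chance was not excluded.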
